A study of Mus musculus with 9 samples.

How the data were processed

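Gene expression was measured by RNA sequencing in 5 libraries of whole mouse midbrain and 4 libraries of midbrain dopaminergic neurons. Per the labels' protocols, RNA was treated with DNase and purified, cDNA was amplified from nanogram amounts of total RNA, sheared and made into libraries, and single-end reads were taken on an Illumina HiSeq instrument with libraries multiplexed in pairs. The labels do not say how the dopaminergic RNA was isolated. The title of the deposited table uses the term bacTRAP, the usual name of a method that captures ribosomes tagged in 1 cell type together with the RNA they carry.

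The values are FPKM made by the authors. Per the submitters' processing notes, TopHat2 2.0.8 and Cufflinks 2.1.1 were used with the mm10 build. The gene annotation, the program options and the handling of strand are not given in the sources used here. The deposited FPKM of the 2 groups differ in form. Values of the dopaminergic libraries have at most 6 significant digits, as Cufflinks writes them. Values of whole midbrain libraries 1 to 5 between 12 and 80 FPKM were whole multiples of 0.0001 divided by 367, 404, 364, 364 and 370, for 100 percent of the values tested and within 0.1 of a step. That is the form a weighted mean of several outputs takes, and no label records such a step. This difference coincides with the groups, so for a single gene any effect of the handling of the files cannot be separated from that of the cell type. Averaging outputs of 1 sample would apply the same weights to all genes, and so would not by itself place Th 34.3-fold higher beside Mbp 26.1-fold lower. An FPKM of exactly 0 can be a failed estimate. Rn45s, the ribosomal RNA precursor, was at 0 in whole midbrain libraries 1 and 5 and in all dopaminergic libraries and at 4512, 6476 and 6501 in whole midbrain libraries 2, 3 and 4, so such genes are only called listed at 0.

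Depth was estimated from single-exon receptor genes, in which the FPKM of 1 read depends only on length and depth, with a mean fragment of 200 bases assumed. Of the 4 to 16 such genes above 0 in a library, between 2 and 7 agreed within 1 percent. For whole midbrain the estimate is rougher, because of the form of the values described above. Symbols were matched to the GENCODE annotation of GRCm38, the same assembly as mm10, for 23051 of the 24487 rows, 22894 of them on the same chromosome. Symbols that named more than 1 row (260 symbols, 750 rows) were kept as separate rows. Exonic length and GC content came from that annotation for 12459 of the genes tested, 95.1 percent. Coordinates are the table's gene spans, counted from 1. Genes whose exons overlap another gene by at least 100 bases were marked, since the libraries are not stated to keep the strand, and 20 of the named genes have such an overlap. Gene symbols are the identifiers in the table.

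The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for 13106 genes with a mean of at least 1 FPKM over the 9 libraries. The moderated test was two-sided, with a mean-variance trend, 7 residual and about 3 prior degrees of freedom, no further scaling and Benjamini-Hochberg adjustment with a threshold of 0.05. A count model was not used, because FPKM are not counts. Gene lists were tested with camera of the same package, two-sided, with a preset correlation of 0.01, for the 31 of 32 lists with at least 4 measured members. Summaries and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The groups, tests, lists, the rule for named genes and all alternatives except the length and GC corrections were set before the data were examined. The rule named the 10 largest rises and the 10 largest falls with an adjusted p under 0.05, groups that do not overlap, a mean of at least 5 FPKM in the higher group and a symbol of a single row that is not the name of a predicted gene, small RNA, microRNA, pseudogene or clone. It also named Th, Slc6a3, Slc18a2 and Ddc, the 2 passing members with the largest change in each list, and up to 2 passing members that went against most of their list. It gave 90 genes, of which some are not reported here. Other list members named in the text (Qdpr, Maoa, Nr4a2, Pitx3, Lmx1b, Otx2, Satb1, Chrna6, Chrnb3, Ntsr1, Ret, Anxa1, Fgf1, Nefl, Nefh and Chat) were chosen after their values were seen.

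The alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 FPKM, leaving out genes listed at 0 in any library, 4 other scalings (quantile normalization, upper-quartile scaling, median centring, and TPM without small RNA and mitochondrial genes), no mean-variance trend, library weights, the replicate number as a block, an estimated correlation in camera, and leaving out each library in turn. Where adjusted p is said below to run in a range or over all settings, the estimated correlation is left out. A correction for exonic length by loess with a span of 0.5 and one for length and GC content with a span of 0.3 were added after seeing the data. So were 10 further gene families, of which the name patterns of 3 were narrowed after a first run. The rule for length alone was changed after its first result from the camera p to the gap between libraries, with the same outcome. For the residual transcripts of other cells an explanation was added after the first one tested had gone past its bound. The method was tested on simulated data for this comparison, with 200 of 13106 genes changed and the same spread of a gene in both groups. It recovered 47.1 percent of 68 genes changed by 0.5 on the log2 scale, 84.8 percent of 66 changed by 1 and 98.5 percent of 66 changed by 2, with 10 false calls among 163. In the real data 74.2 percent of the genes tested passed, so the shares recovered in the simulation need not hold there. A simulated length trend, a straight line in log2 length, gave 4425 false calls, and 8 after the length correction. That count does not show how well the correction removes the trend of the real libraries. No list was called in simulated data without change. Simulated genes vary independently, so that check cannot show false calls of lists whose members move together. In the real libraries the estimated correlation between the genes of a list reached 0.784.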

Results

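RNA sequencing measured gene expression in whole midbrain and in dopaminergic neurons of the midbrain from mice of the C57BL/6 strain. The series holds 9 libraries, 5 of whole midbrain and 4 of dopaminergic neurons, in 1 table of FPKM (read fragments scaled by transcript length and library depth) with 24487 rows named by gene symbol. The deposited table holds no read counts. The lowest length-scaled values of single-exon receptor genes, each taken as 1 read, correspond to about 33.6, 23.0, 16.2, 24.4 and 33.2 megareads for whole midbrain libraries 1 to 5. For dopaminergic libraries 1 to 4 they correspond to 48.6, 47.2, 62.4 and 60.8 megareads. At those depths 1 read per 1000 positions is worth between 0.0160 and 0.0617 FPKM. The FPKM of all rows summed to 309275 to 313252 in whole midbrain libraries 1, 3, 4 and 5, to 409130 in whole midbrain library 2, and to 506466 to 521822 in the dopaminergic libraries. Across genes, log2 values correlated at 0.9897 to 0.9914 (Pearson's r) between dopaminergic libraries and at 0.947 to 0.962 between whole midbrain libraries without library 2. Whole midbrain library 2 correlated at 0.903 to 0.906 with the rest of its group, and libraries of different groups at 0.784 to 0.817. Genes are not independent replicates. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

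The comparison of the dopaminergic neurons with whole midbrain asked which transcripts differ between these cells and the tissue that holds them. The labels do not say how the dopaminergic RNA was isolated. Any effect of that isolation coincides with the groups, so it cannot be told apart from cell type. If ribosomes were captured, as the term bacTRAP in the title of the deposited table would mean, the comparison also sets RNA carried by ribosomes against RNA of the whole tissue. Of 9 genes that make, store and take up dopamine 8 rose in the dopaminergic libraries. All 71 measured markers of astrocytes, oligodendrocytes and their precursors, microglia and blood vessels fell, as did 20 of 21 markers of other kinds of neuron. Camera called each of these lists with a preset correlation and none with an estimated one (adjusted p = 0.0537 to 0.186 with an estimated correlation). Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892776 to 142899966, mm10), was at 1619 ± 121 FPKM (SD, n = 4) in dopaminergic neurons and at 47.2 ± 2.84 (SD, n = 5) in whole midbrain, a 34.3-fold difference. Mbp, a major protein of myelin (chromosome 18, 82475123 to 82585637), was at 69.1 ± 19.6 FPKM in dopaminergic neurons and at 1802 ± 107 in whole midbrain, 26.1-fold lower. Of 13106 genes with a mean of at least 1 FPKM, limma with Benjamini-Hochberg adjustment called 5014 higher and 4717 lower in dopaminergic neurons at an adjusted p under 0.05, and 1983 of the former and 2194 of the latter differed at least 2-fold. Without whole midbrain library 2, which stood apart from its group, the counts were 5646 and 5089, of which 2169 and 2154 differed at least 2-fold. When FPKM was rescaled to TPM they were 2117 and 7579, of which 721 and 4512 differed at least 2-fold. With a minimum mean of 5 FPKM 2493 were lower, 1066 of them at least 2-fold, and with a pseudocount of 5 the genes at least 2-fold lower were 796. All fold changes on the log2 scale below are of log2(FPKM + 1), which understates the change of low genes, and the median over all genes tested was 0.04.

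**Figure D1:**
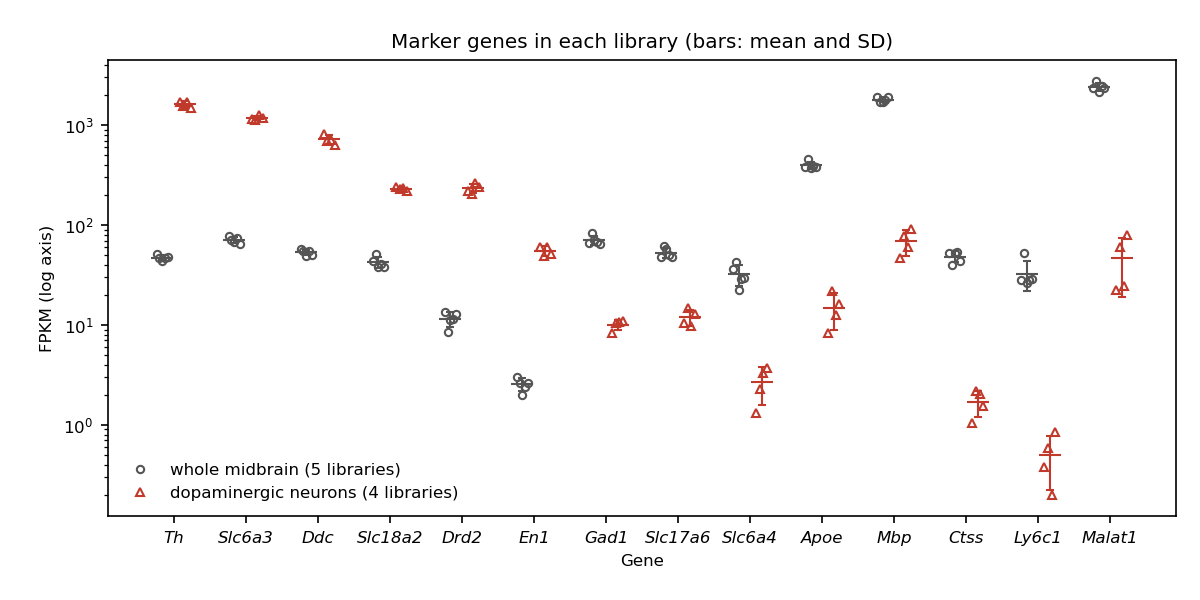
FPKM on a log axis of 14 marker genes in each whole midbrain library (circles) and each dopaminergic library (triangles), with the mean and SD of each group. Th, Slc6a3, Ddc, Slc18a2, Drd2 and En1 lie higher in all 4 dopaminergic libraries than in any whole midbrain library, and the other 8 genes lie lower.

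Of the 9 genes of dopamine synthesis, storage and uptake, 8 rose and none fell. The dopamine transporter gene Slc6a3 (chromosome 13, 73536747 to 73578672) was at 1181 ± 51.6 FPKM in dopaminergic neurons against 71.0 ± 5.15 in whole midbrain. Ddc, the aromatic amino acid decarboxylase (chromosome 11, 11814101 to 11898144), was at 718 ± 72.6 against 53.3 ± 3.22, and Slc18a2, the vesicular monoamine transporter (chromosome 19, 59260878 to 59296012), at 231 ± 8.96 against 42.3 ± 5.28. The log2 fold changes of Th, Slc6a3, Ddc and Slc18a2 were 5.07, 4.04, 3.72 and 2.43, with adjusted p of 1.2e-10, 5.5e-10, 1.0e-09 and 1.4e-08 (limma). The remaining member, Qdpr, which regenerates the cofactor of tyrosine hydroxylase, had a log2 fold change of -0.53 and did not pass. Without whole midbrain library 2, 8 members rose and 1 fell. The list as a whole ranked above the other genes (camera, adjusted p = 0.000116, and adjusted p = 0.150 with an estimated correlation). Of 5 measured genes of dopamine breakdown 3 rose, Aldh1a1 and Maoa among them, and Aldh2 and Maob fell. Aldh1a1, an aldehyde dehydrogenase, was at 1518 ± 180 FPKM in dopaminergic neurons and 205 ± 28.1 in whole midbrain, while Maob, a monoamine oxidase, was at 6.01 ± 1.34 against 13.5 ± 3.99. That list did not differ from the other genes (camera adjusted p = 0.505), and its median of 0.34 became -0.32 when FPKM was rescaled to TPM.

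Of 15 transcription factors of midbrain dopaminergic neurons, 13 rose. The largest changes were those of the forkhead factor Foxa1, at 35.3 ± 1.69 FPKM against 1.06 ± 0.266, and the homeobox gene En1, at 55.3 ± 5.91 against 2.54 ± 0.383. Nr4a2, Pitx3 and Lmx1b, which are needed for the development or upkeep of these neurons, rose by 3.70, 3.69 and 2.94 on the log2 scale. Otx2 had a log2 fold change of -0.27 and did not pass, and without whole midbrain library 2 the list held 13 rises and 2 falls. Ebf1 was called lower at -0.32, a call that ended under quantile normalization (limma adjusted p = 0.449), median centring (0.0503) and length correction (0.900), and its sign turned after length and GC correction (0.01). Over all settings the adjusted p of Ebf1 ran from 9.4e-05 to 0.902. Of 17 receptors and channels of these neurons, 15 rose, led by the dopamine autoreceptor Drd2 (233 ± 25.5 FPKM against 11.5 ± 1.93) and the transporter-like gene Slc10a4 (254 ± 22.3 against 18.3 ± 3.06). The nicotinic receptor subunits Chrna6 and Chrnb3, the neurotensin receptor Ntsr1 and the growth factor receptor Ret rose by 3.62, 3.10, 3.53 and 3.29. The calcium channel gene Cacna1d was lower, at 2.04 ± 0.213 against 3.85 ± 0.269, and its exons share 589 bases with Chdh on the opposite strand. Both lists ranked above the other genes (camera adjusted p = 6.2e-06 for the factors and 2.7e-06 for the receptors and channels), each with adjusted p = 0.0537 with an estimated correlation.

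Outside small RNA and predicted genes, the others with the largest rises were Bahcc1 (82.5 ± 17.8 FPKM against 2.45 ± 0.373), Fam167a (47.8 ± 2.26 against 1.63 ± 0.359), Fam210b (180 ± 11.9 against 10.2 ± 1.28), the synaptotagmin Syt17 (170 ± 11.6 against 9.86 ± 2.52) and the gamma-synuclein gene Sncg (838 ± 50.3 against 54.3 ± 5.89). Of 10 markers reported for dopaminergic neurons of the substantia nigra, 8 rose, among them Sncg, Aldh1a7 (3.42 on the log2 scale) and Anxa1 (3.17). Vcan, a matrix proteoglycan, fell by 1.93, and Fgf1 stood at 0.01. The list ranked above the other genes (camera adjusted p = 0.00169, and adjusted p = 0.176 with an estimated correlation). Of 12 markers reported for the ventral tegmental area, 7 rose and 2 fell. The peptide genes Grp and Cck rose by 2.61 and 2.60 on the log2 scale, with Cck at 512 ± 86.9 FPKM against 84.4 ± 19.1. Slc17a6, a vesicular glutamate transporter, fell by 2.06, and the peptide gene Adcyap1 at 4.79 ± 0.625 against 10.2 ± 1.42. This list did not pass in camera (adjusted p = 0.0591). It passed without the filter on low values (0.0118), under upper-quartile scaling (0.0260) and as TPM (0.00121), and its adjusted p ran from 0.00121 to 0.288 over all settings. Slc17a6 is also on the list of glutamatergic neurons. Both marker lists were compared with whole midbrain and not with each other, so they do not tell which kind of dopaminergic neuron was sampled.

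Of 20 genes of synaptic vesicle exocytosis, 12 rose and 2 fell. The complexin gene Cplx1 was at 2097 ± 113 FPKM against 265 ± 63.0. In whole midbrain library 2 it stood at 376 FPKM, above the 225 to 253 of the rest of its group. Syn2 and Syt11 fell by 1.32 and 0.64 on the log2 scale. The list passed in camera (adjusted p = 0.00258, and adjusted p = 0.0537 with an estimated correlation) and did not pass under quantile normalization (0.572), with a range from 0.000103 to 0.572 over all settings. Among 15 pan-neuronal genes 8 rose, or 10 adjusted over the list alone, and 4 fell. Gap43, a growth cone protein, was at 818 ± 25.8 FPKM against 156 ± 6.46. The dendritic protein gene Map2 (15.4 ± 0.909 against 81.5 ± 10.3) and the neurofilament genes Nefm, Nefl and Nefh were lower, and the exons of Nefm share 1108 bases with Nefl on the opposite strand. The pan-neuronal list did not pass (camera adjusted p = 0.0807, with a range from 0.0170 without the filter on low values to 0.817 over all settings), and its median of 0.48 became -0.18 as TPM.

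The markers of other neurons were lower. Across 3 lists of GABAergic, glutamatergic, and serotonergic, noradrenergic and cholinergic genes, 20 of 21 measured members fell and none rose. Gad1 and Gad2, the enzymes that make GABA, were at 10.1 ± 1.17 FPKM against 70.3 ± 7.08 and at 29.5 ± 2.94 against 166 ± 25.7. The glutamate transporters Slc17a7 and Slc17a6 fell by 2.14 and 2.06 on the log2 scale. The serotonin transporter Slc6a4 was at 2.67 ± 1.09 against 32.0 ± 7.71, and the serotonin-synthesizing enzyme Tph2 at 7.71 ± 1.79 against 38.6 ± 16.3. Chat, the acetylcholine-synthesizing enzyme, did not pass at -0.17. The GABAergic list had a camera adjusted p of 7.2e-05, the glutamatergic list 0.0216 and the third 0.00998, and with an estimated correlation the adjusted p was 0.164, 0.126 and 0.186. As TPM the glutamatergic list did not pass (camera adjusted p = 0.0712, the highest of a range that began at 0.0122 and leaves out the estimated correlation). Of 13 neuropeptide genes, 10 fell, with Grp and Cck as the 2 that rose. The neuropeptide list missed the threshold (camera adjusted p = 0.0557) and passed without whole midbrain library 2 (0.0477), whole midbrain library 5 (0.0489) or dopaminergic library 4 (0.0474). It also passed with a minimum mean of 5 FPKM (0.0352), without genes listed at 0 (0.0491), under median centring (0.0383) and after length correction (0.0142), in a range from 0.0142 to 0.340. With an estimated correlation, which that range leaves out, its camera adjusted p was 0.426.

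Every one of the 71 measured markers in 6 lists of glial and vascular cells fell. Among astrocyte genes, Apoe, which encodes a lipid carrier, was at 14.9 ± 5.85 FPKM against 396 ± 34.2. The myelin gene Mbp fell by 4.73 on the log2 scale. Outside the list Bcas1, also known from oligodendrocytes, fell by 4.78, and its exons share 440 bases with an antisense gene. Among precursors of oligodendrocytes, Pdgfra fell by 2.30 and Gpr17 fell by 1.78, which share 456 and 188 exonic bases with genes on the opposite strand. The microglial genes Ctss and C1qb were at 1.69 ± 0.506 against 48.4 ± 6.15 and at 1.62 ± 0.863 against 31.9 ± 6.85. Ly6c1 and Slco1a4 of endothelial cells fell by 4.45 and 3.99, and Rgs5 and Vtn of mural cells stood at -3.97 and -3.90. In camera the 6 lists had adjusted p of 2.2e-08 (astrocytes), 6.0e-08 (oligodendrocytes), 0.00212 (precursors), 7.5e-07 (microglia), 8.7e-07 (endothelial) and 0.000475 (mural). With an estimated correlation the adjusted p was 0.164 for oligodendrocytes and 0.0537 for each of the other 5.

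The percent of the whole midbrain level left in the dopaminergic libraries differed between the lists. In dopaminergic libraries 1 to 4 the median oligodendrocyte gene stood at 11.6, 16.6, 11.6 and 20.2 percent of its whole midbrain mean. The median astrocyte gene stood at 4.56, 5.58, 5.16 and 7.51 percent and the median endothelial gene at 1.11, 2.11, 0.767 and 2.59 percent. Malat1 followed at 22.5, 60.3, 24.5 and 78.7 FPKM and Mbp at 47.2, 76.8, 60.3 and 92.3 FPKM.

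**Figure D2:**
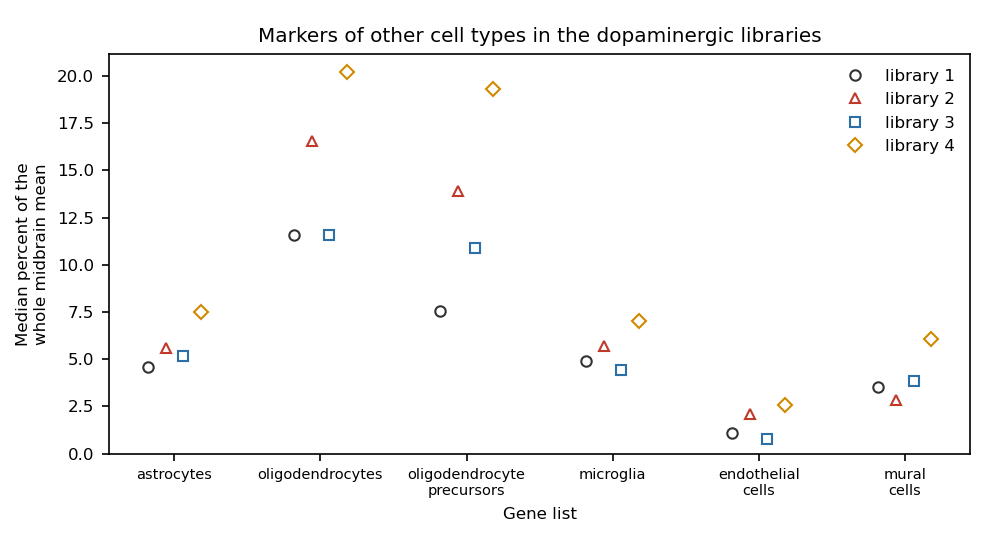
Median over each list's genes of FPKM as a percent of the whole midbrain mean, for dopaminergic libraries 1 to 4, with 1 symbol per library. Library 4 is the highest in all 6 lists, at 20.2 percent for oligodendrocytes and 2.59 percent for endothelial cells.

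All 4 measured genes of meningeal fibroblasts fell, among them Dcn (1.07 ± 0.339 FPKM against 16.8 ± 7.20) and Igf2 (5.20 ± 2.86 against 36.9 ± 18.5), whose exons share 3596 bases with Gm49394 on the same strand. Of 5 measured genes of ependymal and choroid plexus cells 3 fell, with Rarres2, which shares 892 exonic bases with Lrrc61, at -2.31 and Tmem212 at -1.45. The call of Tmem212 ended without whole midbrain library 3 or 4 (limma adjusted p = 0.0844 and 0.0574) or dopaminergic library 1, 3 or 4 (0.0861, 0.0824 and 0.0824). It also ended with a pseudocount of 5 (0.0723), without the filter on low values (0.0602), under quantile normalization (0.244) and with library weights (0.0538), in a range from 0.00125 to 0.244. Of 4 measured red blood cell genes 3 fell, or 4 adjusted over the list alone, where the added gene had the largest fall. The 3 were led by the beta-globin genes Hbb-bt and Hbb-b1 (-2.55 and -2.48). These near-identical genes can share reads. Those 3 lists did not pass in camera (adjusted p = 0.0557, 0.141 and 0.0557). The meningeal list passed without whole midbrain library 3 (0.0122), with a pseudocount of 0.1 (0.0439), without the filter on low values (0.0335), without genes listed at 0 (0.0492) and under median centring (0.0409), in a range from 0.0122 to 0.145. With an estimated correlation, which that range leaves out, its camera adjusted p was 0.349. The red blood cell list passed without whole midbrain library 3 (0.0444) or dopaminergic library 4 (0.0474), without genes listed at 0 (0.0491), under quantile normalization (0.0419) and under median centring (0.0409), in a range from 0.0409 to 0.170. With an estimated correlation its camera adjusted p was 0.260.

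Several further gene families rose together. Of 75 measured nuclear-encoded subunits of the respiratory chain 67 rose and 3 fell, with a median log2 fold change of 1.51. Ndufv3 of complex I rose by 2.92 on the log2 scale, and Ndufs5 was at 84.0 ± 12.8 FPKM against 14.4 ± 8.29, with whole midbrain library 3 at 0.000375. Ndufs1 and Ndufa4l2 fell by 0.86 each, and the latter did not pass under quantile normalization (limma adjusted p = 0.304, in a range from 1.8e-05 to 0.304). Of 74 cytosolic ribosomal protein genes 70 rose and 1 fell (median 1.23), with Rpl26 at 61.5 ± 4.79 FPKM against 7.79 ± 4.28, Rps27 up by 2.81 and Rpl21 down at -1.35. Many of these genes have near-identical pseudogenes, so the split of reads among copies is uncertain. Of 37 proteasome subunits 29 rose and none fell (median 0.75), against 19 and 4 under quantile normalization and 14 and 8 as TPM, led by Psmb10 and Psmb1 (1.72 and 1.57). Of 38 measured replication-dependent histone genes 34 rose and 2 fell (median 1.60), with Hist1h4d and Hist3h2ba at 3.09 and 3.08 and Hist1h2bc and Hist2h2be at -1.41 and -1.22. In camera the adjusted p was 5.1e-08 for the respiratory chain, 3.5e-09 for ribosomal proteins, 1.3e-05 for the proteasome and 1.3e-07 for histones, and with an estimated correlation the adjusted p was 0.349, 0.306, 0.280 and 0.0537. Under quantile normalization the ribosomal protein list (median 0.24, adjusted p = 0.118) and the proteasome list (median 0.36, adjusted p = 0.0778) did not pass. Leaving out the estimated correlation, these were the highest values of ranges that began at 2.1e-17 and 7.6e-08.

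Whole midbrain library 2 stood apart from its group in several of these genes, on the side of the dopaminergic libraries in some and on the other side in others. Ndufv3 was at 171 FPKM there and at 84.4 to 94.1 in the rest of the group, Psmb10 at 26.7 against 11.9 to 13.4, and Hist1h4d at 121 against 38.0 to 52.1, all nearer to the dopaminergic level. Rpl21 at 154 against 118 to 125, Hist1h2bc at 52.4 against 22.6 to 27.0 and Hist3h2ba at 5.66 against 8.86 to 12.3 were farther from it. Without that library 68, 71, 35 and 34 members of the 4 lists rose. The difference between the groups also followed transcript length. Among the shortest of 10 equal groups of genes by length, of up to 1636 exonic bases, the median log2 fold change was 0.68, and in the longest group it was -0.47. After a correction for length, chosen after seeing the data, the medians of the 4 lists were 0.84, 0.77, 0.50 and 0.77, with adjusted p = 0.256, 0.192, 0.169 and 0.184 with an estimated correlation.

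**Figure D3:**
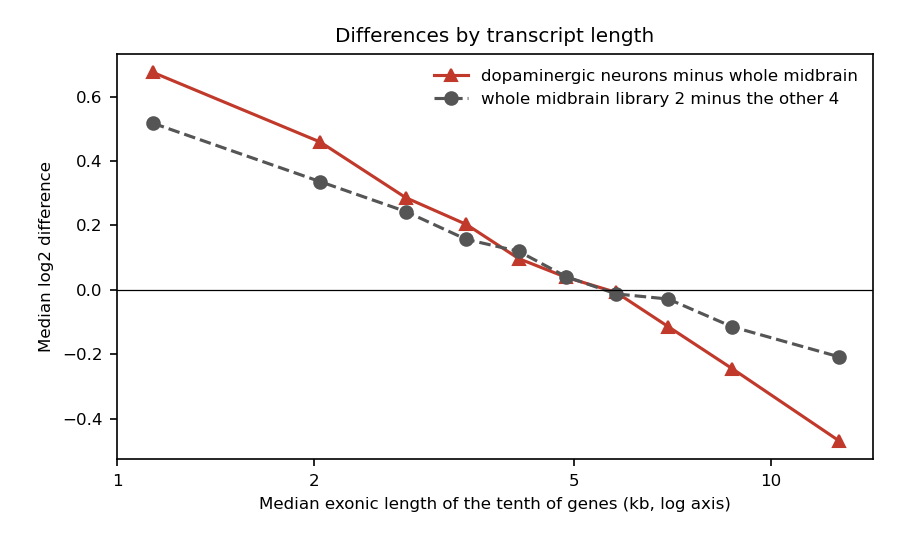
Median log2 difference in each of 10 equal groups of genes by exonic length (x axis in kb, log scale), for dopaminergic neurons minus whole midbrain (triangles) and for whole midbrain library 2 minus the other 4 whole midbrain libraries (circles). The first falls from 0.68 to -0.47 and the second from 0.52 to -0.21.

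All 8 measured members of a list of nuclear long noncoding RNAs fell, with a median of -4.22 (camera adjusted p = 7.2e-06, and adjusted p = 0.0814 with an estimated correlation). Malat1 (chromosome 19, 5795690 to 5802671) was at 46.5 ± 27.6 FPKM against 2420 ± 227, Meg3 (chromosome 12, 109540996 to 109571729) at 9.01 ± 3.24 against 450 ± 20.4 and Snhg11 at 9.63 ± 1.44 against 441, with 626 in whole midbrain library 2. Snhg11 is annotated as protein coding in GENCODE. Malat1 and Meg3 share 453 and 1228 exonic bases with genes on the opposite strand. Outside small RNA and predicted genes, the others with the largest falls were Zfp488 (0.807 ± 0.226 against 117 ± 20.0), Dcdc2c (57.1 ± 12.3 in whole midbrain and at most 0.0850 in dopaminergic libraries), Sparc (13.9 ± 5.19 against 563 ± 129) and Ccdc82 (0.410 ± 0.0502 against 44.5 ± 5.56). Small RNA genes were listed by patterns of their names, which also take in host transcripts. The protocols given above name no step for small RNAs, so these FPKM need not be levels of the small RNAs themselves. Of 117 measured genes of this list 41 fell, or 27 adjusted over the list alone, and 3 rose (camera adjusted p = 0.00118, and adjusted p = 0.0771 with an estimated correlation). Mir1188 and Snora31 were listed at 0 in all 4 dopaminergic libraries, and Mir1188 at 1111 to 1203 FPKM in whole midbrain. Mir22hg, the host transcript of a microRNA, rose by 0.95. Mir6244, inside Zc3h12c, was listed at 0 in 4 whole midbrain libraries, at 112 FPKM in whole midbrain library 1 and at 92.5 to 120 in the dopaminergic libraries. The list's median of -2.02 became 0.92 among genes listed above 0 in every library, with adjusted p = 0.371, the highest of a range that began at 1.5e-05. No mitochondrially encoded gene was in the table.

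Of 9 measured immediate early genes 5 fell, led by Egr1 (3.19 ± 0.784 FPKM against 20.9 ± 1.73) and Fos (0.680 ± 0.225 against 5.50 ± 2.31), and Btg2 rose by 0.65. That rise did not pass as TPM (limma adjusted p = 0.621, in a range from 9.1e-05 to 0.621). The list missed the threshold (camera adjusted p = 0.0637) and passed without the filter on low values (0.0332), after length correction (0.0155) and after length and GC correction (0.0120), in a range from 0.0120 to 0.426. All 4 Y-linked genes fell, with Eif2s3y and Kdm5d at -1.56 and -1.44. That list's camera adjusted p of 0.0465 (adjusted p = 0.152 with an estimated correlation) moved past the threshold without whole midbrain library 3 (0.0520) or 4 (0.0502), under quantile normalization (0.0626), under upper-quartile scaling (0.0629), as TPM (0.120), after length correction (0.0769) and after length and GC correction (0.123). Leaving out the estimated correlation, the range was from 0.0359 to 0.123.

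Among 18 genes linked to Parkinson's disease 8 rose and 4 fell. The ubiquitin hydrolase gene Uchl1 was at 1334 ± 78.1 FPKM against 296 ± 60.7. Vps13c was at 2.99 ± 0.281 against 10.3 ± 0.917, and Fbxo7 fell by 0.88 on the log2 scale. The list did not differ from the other genes (camera adjusted p = 0.337), and its median of 0.16 became -0.08 under upper-quartile scaling and -0.52 as TPM. Of 18 genes of antioxidant defence 11 rose and 2 fell. Txn1 (thioredoxin) was at 228 ± 3.82 FPKM against 73.1 ± 28.7, with 124 in whole midbrain library 2 and 56.4 to 63.7 in the rest of that group. Nfe2l2, a regulator of antioxidant genes, and Cat (catalase) fell by 1.90 and 0.96. The list's camera adjusted p was 0.0127, and adjusted p = 0.260 with an estimated correlation. It did not pass with a minimum mean of 5 FPKM (0.0563) or under quantile normalization (0.118), in a range from 0.000690 to 0.118 that leaves out the estimated correlation. Its median of 0.62 became -0.03 as TPM, where camera still placed it above the other genes.

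**Figure D4:**
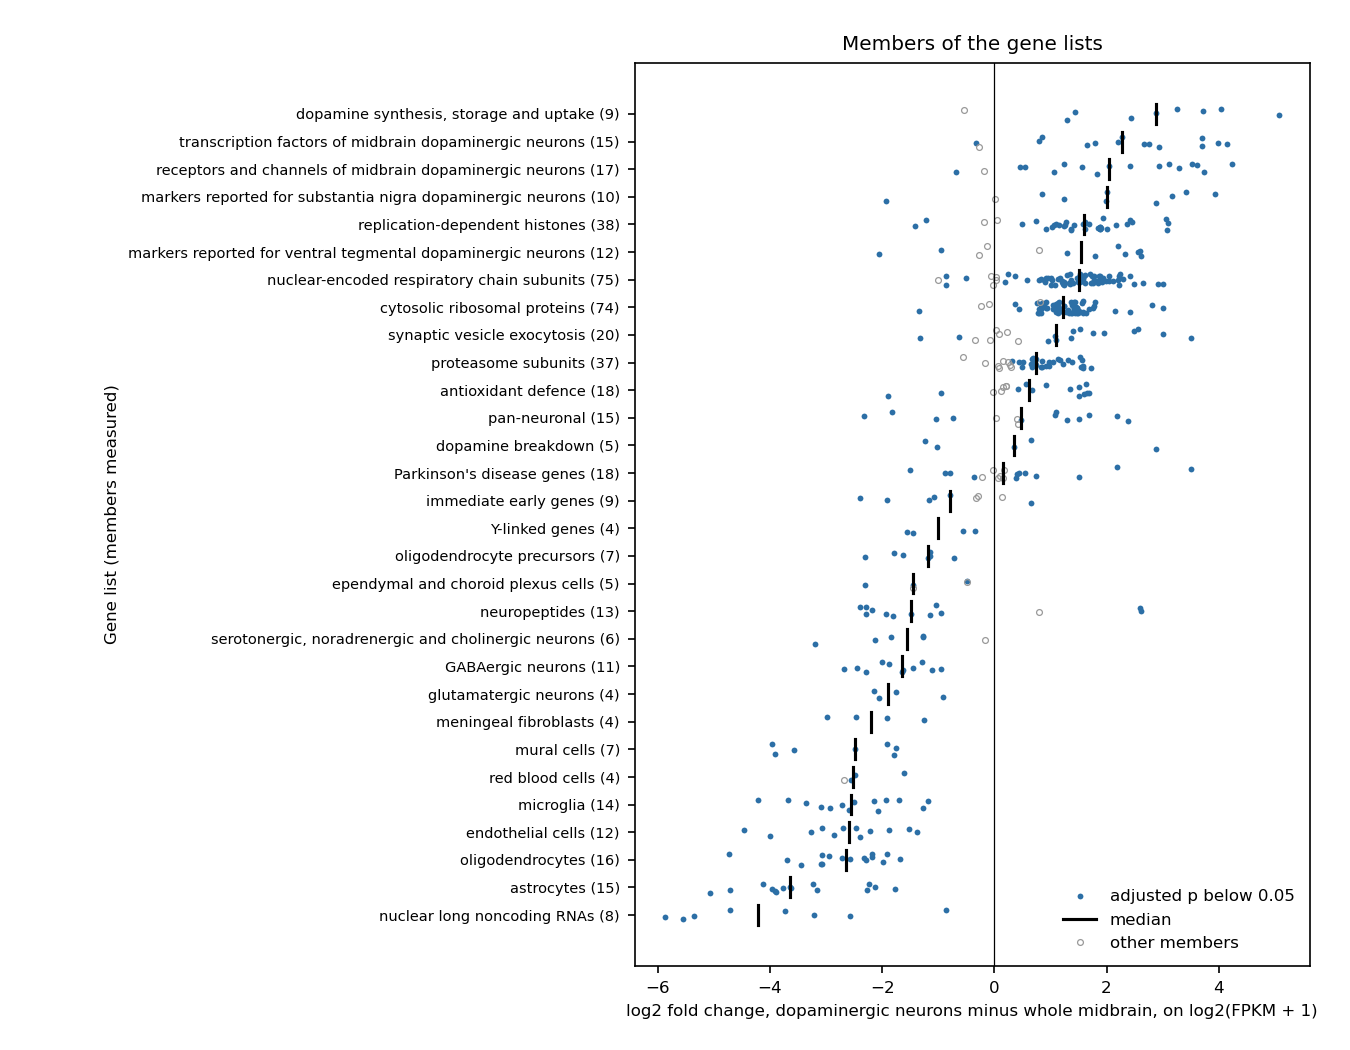
Log2 fold change (x axis, dopaminergic neurons minus whole midbrain) of each measured member of 30 gene lists, with members at an adjusted p under 0.05 filled, the others open and the median as a bar. The medians run from -4.22 for nuclear long noncoding RNAs to 2.87 for dopamine synthesis, storage and uptake, and those of the Parkinson's disease, dopamine breakdown, pan-neuronal and antioxidant lists turn negative as TPM, that of the Parkinson's disease list also under upper-quartile scaling.

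In all, camera called 22 of 31 lists, 10 higher and 12 lower, with the correlation between genes preset at 0.01. With an estimated correlation it called 0, and the adjusted p of those 22 lists ran from 0.0537 to 0.349, with 12 lists at an unadjusted p under 0.05. The counts of 3 lists differed when adjusted over the list alone. The libraries of the groups did not overlap in FPKM for 8442 genes, 64.4 percent of those tested, where chance gives 1.59 percent. The split of the calls moved with the scaling and with the filter on low values. Higher genes made up 51.5 percent of calls as deposited (5014 higher, 4717 lower), 40.6 percent under upper-quartile scaling (3872 higher, 5673 lower) and 21.8 percent as TPM (2117 higher, 7579 lower). They made up 62.6 percent with a minimum mean of 5 FPKM (4177 higher, 2493 lower) and 43.1 percent without a filter (5200 higher, 6877 lower). The median of all genes moved from 0.04 to 0.11 under quantile normalization and under median centring, to -0.16 under upper-quartile scaling and to -0.58 as TPM.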

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

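The tests of the long noncoding genes were set before their results were seen, and those of length, of the residual transcripts and of other splits were chosen after. A library is named in the next paragraph, and kept in all values unless the text says otherwise, where its gap to the nearest library of its group, as a share of the group's range, exceeded Dixon's critical value. Of 176 group values tested 31 did (17.6 percent), where chance gives about 1 in 20, and 23 of them were in whole midbrain library 2.

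Whole midbrain library 2 lay above its group in the FPKM total (409130) and in the FPKM of Meg3 (486), Snhg11 (626), Sparc (793), Adcyap1 (12.6), Nefm (173), Cplx1 (376), Syt11 (163), Apoe (456), Ly6c1 (52.2), Uchl1 (401), Txn1 (124), Fos (9.60), Ndufv3 (171), Rpl21 (154), Psmb10 (26.7), Psmb1 (93.6), Hist1h4d (121) and Hist1h2bc (52.4). It lay below its group in Gad2 (121), Map2 (63.5), Rgs5 (12.999) and Vps13c (8.66). Whole midbrain library 3 was low in Vtn (21.0) and Ndufs5 (0.000375), and whole midbrain library 1 was alone above 0 in Mir6244 (112). Dopaminergic library 2 was high in Slco1a4 (0.236) and Tmem212 (0.701), library 1 was high in Rarres2 (1.14) and low in Eif2s3y (3.42), and library 4 was low in Mir6244 (92.5).

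Shorter transcripts were higher in dopaminergic libraries, with a Spearman rho of -0.254 between log2 fold change and exonic length across 12459 genes, which are not independent. The handling of transcript ends in short transcripts would leave no trend among long ones, but rho was -0.219 among 8896 genes of at least 3000 bases. Length alone, as corrected here, does not account for all of the rise of these families: after the correction the medians were 0.839 for respiratory chain subunits, 0.774 for ribosomal proteins and 0.499 for proteasome subunits (camera adjusted p = 1.9e-06, 2.8e-07 and 0.000393, and adjusted p = 0.256, 0.192 and 0.169 with an estimated correlation). In each family every dopaminergic library then lay above every whole midbrain library, by at least 0.307, 0.299 and 0.297 respectively on the log2 scale. Whole midbrain library 2 still stood apart, with medians of 0.14, 0.07 and -0.07 relative to the mean of all libraries. The rest of its group stood at -0.55 to -0.41, -0.49 to -0.38 and -0.34 to -0.21, so a shift in the same direction appeared within 1 tissue. A length bias between libraries that needs no difference in cell type may explain the trend itself and cannot be told apart from the groups, since whole midbrain library 2 against the rest of its group gave -0.323 within 1 tissue, and a biological difference stays open and untested.

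Transcripts of glia and vessels left in the dopaminergic libraries may be RNA carried over from other cells, all 71 marker genes being measured in whole midbrain. An even carry-over of whole midbrain RNA as the only source is argued against by the differences between the 6 lists in the percent left (permutation p = 1e-05, the smallest that 100000 permutations can give). That p treats the 71 genes as independent, which genes of 1 cell type are not, and it does not measure the spread between samples. Library 4 was the highest in 6 of 6 lists, where expression in dopaminergic neurons at each gene's own level as the only source was bounded at 3. A different amount of carried-over RNA in each library was put forward only after that result, and the pair cannot be told apart here, because the test rests on 1 library picked from these values and on lists that share libraries. Mbp, an abundant gene among these, was at 92.3 FPKM in that library, and the labels name no sort or gate.

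Long noncoding genes as a class were lower in dopaminergic libraries in 177 and higher in 94 of 395 genes, with a median of -0.22. Low expression level may be enough for that median as deposited, which lay at percentile 89.9 of 10000 random lists of protein-coding genes matched on mean expression, but not after length correction, where the median of -0.583 lay at percentile 0. The same value argues against transcript length, as corrected here with lengths from GENCODE, as the source of the low median. Before that correction these genes did not lie below their matched lists. The 196 genes without exon overlap had a median of -0.406, so overlap with other genes' reads is not needed for a low median. Whether overlap adds to it stays open, because those genes were not matched on expression. Matched protein-coding lists for all 395 genes had a median of -0.290. Loss of nuclear RNA through capture of ribosomes stays an untested explanation for the much larger falls of Malat1, Meg3 and the other members of the list fixed in advance.

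Other splits of the 9 libraries into groups of 4 and 5 were tried, 100 of the 126 possible, the real one included. Only the real split gave as many higher genes (5014, highest other 3210), lower genes (4717, highest other 3005), genes at least 2-fold higher (1983, highest other 1632) and genes at least 2-fold lower (2194, highest other 1170), 1 of 100 in each case. The 96 splits with 1 to 3 dopaminergic libraries in the group of 4 mix the cell types, which widens the spread within groups, and 92 of them gave 0 genes. The splits are therefore no clean reference for these counts, and no conclusion on chance is drawn from them. Nor can they tell cell type from anything else that coincides with the groups. For the number of lists called, 32 of 100 splits gave at least the real 22 (highest other 26), so by that count chance is not excluded. The splits are no clean reference for that number, because those as large held 0, 1 or 3 dopaminergic libraries in the group of 4 and so still part the cell types unevenly, while the 47 splits with 2 gave at most 9 lists.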

How the results depend on the processing

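The corrections for length and GC content were chosen after seeing the data. The 4 counts of genes stayed within 1.5 times of their value under most settings. Without each library in turn they ran from 4712 to 5646 (higher), 4483 to 5089 (lower), 1942 to 2169 (at least 2-fold higher) and 2124 to 2201 (at least 2-fold lower), and the lists called from 21 to 24. With a pseudocount of 5 the genes at least 2-fold lower were 796, since it shrinks the change of low genes. With a minimum mean of 5 FPKM, which tests fewer genes, 2493 were lower and 1066 at least 2-fold lower. As TPM without small RNA and mitochondrial genes 2117 were higher, 7579 lower, 721 at least 2-fold higher and 4512 at least 2-fold lower. That setting rescales libraries whose FPKM totals differ between the groups. Camera with an estimated correlation called 0 lists (12 at an unadjusted p under 0.05), and 0 after the length correction as well (12).

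List medians changed sign for small RNA genes without genes listed at 0 (0.917), for Parkinson's disease genes under upper-quartile scaling (-0.0754) and as TPM (-0.521), and as TPM for dopamine breakdown (-0.325), pan-neuronal (-0.185) and antioxidant genes (-0.0282). Of the named genes, Ebf1 changed sign after length and GC correction (0.0132). The cause of these changes was not tested. With planned settings, named genes kept their side of the threshold in 1858 gene and setting pairs and lost it in 14, all in the same direction as before.

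The groups share replicate numbers 1 to 4, but same-numbered libraries did not deviate together (correlations of -0.0389, -0.0498, 0.0067 and 0.019) and 0 dopaminergic libraries came closest to their own number. With a replicate block 4554 genes were higher and 4355 lower, with 3 residual degrees of freedom. The block ended the call of Ebf1 (adjusted p = 0.0635) and brought 4 lists past the threshold, neuropeptides (0.0278), meningeal fibroblasts (0.0353), red blood cells (0.0434) and immediate early genes (0.0491), and it changed no other call among named genes and lists. Of all genes, 8842 were called in the same direction with and without the block and 0 in opposite directions. Some other settings did turn calls of genes. As TPM 368 genes were called in the opposite direction (6793 in the same), and under quantile normalization 95 (7766 in the same). After length correction 53 turned (7931 in the same direction), and after length and GC correction 73 (7921 in the same). Depth limits low genes most, since 1 read per 1000 positions is worth up to 0.0617 FPKM.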

Other observations

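The gene families in this part were chosen after seeing the data, 10 in all, and tested in the same way. Their camera adjusted p-values cover only these 10 lists and not that choice, so they describe the families and are no independent test of them. Receptors of the main fast transmitters were lower in the dopaminergic libraries, as were the markers of other cells, with medians from -1.56 to -1.90 in the 3 lists of other neurons and from -1.19 to -3.65 in the 6 lists of glia and vessels. How much of the fall came with those cells was not tested. Of 12 measured GABA-A receptor subunits 11 fell, among them Gabrb2, which fell by 1.89 on the log2 scale, and Gabra4 rose by 1.47 (median -1.25, or -1.04 after length correction, camera adjusted p = 0.000862, and adjusted p = 0.184 with an estimated correlation). Of 22 glutamate receptor subunits 18 fell and 2 rose, with Gria2 at -1.83, Grm3 at -2.48 and Grik3 at 1.27 (median -0.94, or -0.67 after length correction, camera adjusted p = 0.000461, and adjusted p = 0.213 with an estimated correlation). Of 59 potassium channel subunits and interacting proteins 35 fell and 10 rose. Kcnj10, a channel of glia, fell by 3.67, and Kcns3, Kcnip4 and Kcnj5 stood at 2.36, 1.63 and -0.81 (median -0.60, or -0.55 after length correction, camera adjusted p = 0.00197, and adjusted p = 0.184 with an estimated correlation). Of 36 semaphorins, plexins, ephrins and Eph receptors, which guide axons, 22 fell and 3 rose, with Plxnb1 at -2.55 (median -0.57, or -0.39 after length correction, camera adjusted p = 0.00115, and adjusted p = 0.184 with an estimated correlation).

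Of 77 mitochondrial ribosomal protein genes 73 rose and none fell (1 fell under upper-quartile scaling and 6 as TPM), with a median of 1.35, or 0.89 after length correction (camera adjusted p = 1.5e-13, and adjusted p = 0.201 with an estimated correlation). Of 14 tubulins 12 rose and none fell, against 8 and 2 under quantile normalization and 7 and 2 as TPM, with Tuba1a at 1.47 and Tubb2b at 1.45 (camera adjusted p = 0.000881, and adjusted p = 0.184 with an estimated correlation). The medians of these 6 families kept their sign under the 4 other scalings and the length correction. Glycolysis enzymes (8 of 16 higher, 4 lower), sodium channel subunits (2 of 9 higher, 5 lower), calcium channel subunits (5 of 21 higher, 9 lower) and V-ATPase subunits (11 of 18 higher, 3 lower) did not pass in camera (adjusted p = 0.279, 0.194, 0.451 and 0.0975). Under quantile normalization 1 glycolysis enzyme was higher and 8 lower, and as TPM 2 were higher and 8 lower. Of V-ATPase subunits 5 were higher and 6 lower under quantile normalization, and 6 higher and 7 lower as TPM. The median of glycolysis enzymes turned from 0.42 to -0.35 under quantile normalization and -0.27 as TPM, that of V-ATPase subunits from 0.70 to -0.07 under quantile normalization, and that of calcium channel subunits from -0.16 to 0.09 after length correction.

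Gapdh, often used as a reference gene, was at 254 ± 22.6 FPKM (SD, n = 4) in dopaminergic neurons and at 1725 ± 298 (SD, n = 5) in whole midbrain, a log2 fold change of -2.74 that ran to -3.45 under quantile normalization. The cause of this difference was not tested, and the program options that set how shared reads are split are not given. Of other glycolysis enzymes, 3 were also lower: Aldoc, a member of the astrocyte list, all of whose members fell, at -1.77, Pfkp at -0.62 and Pfkm at -0.42 (-2.69, -0.94 and -0.95 under quantile normalization). Pfkp was at -0.17 after length correction and no longer passed (limma adjusted p = 0.116). Of the 8 that were higher, Aldoa, Tpi1, Pgam1 and Pgk1 stood at 1.17, 1.04, 0.96 and 0.42, and at 0.00, 0.19, -0.20 and -0.44 under quantile normalization. Pgk1 was also at -0.26 as TPM. The genome-organizing factor Satb1, on the fixed list of transcription factors, was at 64.4 ± 2.27 FPKM against 9.41 ± 1.54.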
